A study of Rattus norvegicus with 16 samples.

How the data were processed

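Total RNA from kidney cortex of male wild-type and BRCA1+/- rats was labelled with Cy3 and hybridised to a single-colour Agilent whole rat genome array, 1 array per sample. The 16 arrays fall into 6 groups: untreated control (2 arrays), Fe-NTA for 1 week (3) and Fe-NTA for 3 weeks (3) in each genotype. Per the labels the first 2 doses were 5 mg iron/kg, the last 3 of the first week 7 mg iron/kg and those of weeks 2 and 3 10 mg iron/kg. The protocol began with 17 wild-type and 18 BRCA1+/- rats, and how the arrayed animals were chosen from them is not given in the sources used here.

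Per the file headers, each scanner file holds spot intensity values made with Agilent Feature Extraction 10.7: a processed signal that is background-subtracted and spatially detrended, with a substitute value for dim spots, and the mean spot and local background intensity, none of them scaled between arrays. Per the file headers the files also hold other columns, flags for control spots, outlier spots and spots well above background. The authors' deposited value table holds log2 values. Compared with the scanner files, these are the log2 processed signal minus the 75th percentile of the array over the 45738 probes listed, without centring per gene. The scaling step itself is not named in the sources used here.

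The analysis began from the scanner files. Each array has 62976 spots, of which 4259 control spots and the spots marked as outliers were left out. Spots of the same probe were averaged, giving 45598 probes. The value used is log2 of the processed signal minus the 75th percentile of the array over non-control probes. The 21229 probes whose sequence accession was in the reference gene table took its symbol, which changed the name of 2233 of them. Another 132 were renamed through another probe of the same name, and 24237 kept the name in the file. A gene is represented by its probe with the highest mean over all arrays, and probes were kept where they were well above background on every array of at least 1 group. Of 45483 probes with a value on all arrays 20431 passed, leaving 16008 genes tested, 11463 of them with a plain symbol. Where a gene was well above background on no array of a group its value there is a substitute, so the change is given as a lower bound ("at least N-fold"), the mean of the other group against a detection limit of -1.05 on the scaled log2 scale, in place of the log2 fold change. This limit is the highest over the 16 arrays of the lowest signal well above background. Detection was counted over all probes of a gene and asked for only 1 array of the group. A log2 fold change can therefore still rest in part on substitute values of the probe used.

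Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group and a shared spread, 10 residual and 4.87 prior degrees of freedom, and Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. All tests are two-sided. Every p without another name is an adjusted p, from limma for a gene and from camera (below) for a list. The p-values of the linear model of erythroid genes and array brightness are unadjusted. The comparisons were each treated group with the controls of its genotype, 3 weeks with 1 week within genotype, the genotypes within each condition and on average, and the interactions of genotype with treatment at 1 and 3 weeks. The median residual SD was 0.395 on the log2 scale. The 25 gene lists of cell types and processes, written from general knowledge before the data were examined, as were the comparisons and the tests, were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 25 lists, and with fry for direction. They were iron handling, NRF2 targets and glutathione enzymes, ferroptosis regulators, tubular injury and repair, p53 targets, homologous recombination and BRCA1 partners, cell cycle, proximal tubule, thick ascending limb and distal convoluted tubule (called distal), collecting duct, podocyte, endothelium, fibroblast and matrix, macrophage, lymphocyte, neutrophil and mast cell, erythroid, adrenal and adipose, chemokines and cytokines, interferon response, fatty acid oxidation, oxidative phosphorylation, integrated stress and unfolded protein response, heat shock and metallothionein, and lysosome and autophagy. Numbers in brackets after a list's count of genes are adjusted over the list alone.

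Named genes follow a rule fixed with the lists: Brca1; for treatment and time the 8 up and 8 down with the largest change among called genes whose groups do not overlap; for genotype 10 and 10; the 2 members of each list with the smallest p (for genotype, of each list called); and for the interactions the 10 with the smallest p among called genes plus Slc7a11, Tfrc, Hmox1, Gpx4, Cdkn1a and Havcr1. Some genes the rule names are not reported here, and the counts of named-gene values under the alternatives include them.

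The alternatives were normexp background correction (offset 50) of the mean signal, quantile normalization, no filter on dim probes, every probe on its own, the authors' value table, the slide as a block, the replicate number as a block, eBayes with trend and robust, only the groups of the comparison, the estimated correlation, and leaving out each array. Chosen after the data were seen were only probes well above background on all arrays, values floored at that detection limit, scaling on the median of probes well above background, and the slide as a block for the lists. The arrays lie on 2 slides of 8, each with at least 1 array of every group, and each comparison was repeated within each slide. Genotype is not balanced over them: slide 1 holds 3 heterozygous and 5 wild-type arrays, and slide 2 holds 5 and 3. A within-slide fit has 1 or 2 arrays per group and 2 residual degrees of freedom, so a low count there can follow from the few arrays.

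Recovery was tested on simulated data: in 50 genes per size changed by 0.5, 1, 2 or 3 on the log2 scale, limma called 2, 14, 68 and 88% for wild-type cortex after 1 week and 0, 0, 42 and 80% for the interaction at 1 week. It also called 6 and 8 unchanged genes. No other genes were changed, far fewer than the 4341 called in the real wild-type comparison after 1 week. The adjustment is stricter with few changed genes, so the percentages do not give the recovery in that comparison. A list of 30 genes shifted by 0.5 was called at adjusted p 5.1e-09 with the preset and 0.0014 with the estimated correlation, and camera with the preset also called 1 of the 24 other lists, which were not shifted. The simulated genes varied independently and the lists were random, so this does not show how either setting performs on lists of correlated genes. Chromosome positions, the BRCA1 mutation itself, probes without a plain symbol and pathology were not analysed here.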

Results

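Gene expression was measured in kidney cortex of male rats on 16 single-colour Agilent arrays, 8 from wild-type animals and 8 from animals heterozygous for a BRCA1 mutation (BRCA1+/-, called heterozygous from here on). BRCA1 is a gene of DNA repair by homologous recombination. Fe-NTA (ferric nitrilotriacetate) is an iron chelate that causes oxidative injury of the proximal tubule. Rats received it by intraperitoneal injection from 4 weeks of age, 5 times a week, for 1 or 3 weeks, and cortex was taken 48 h after the last injection. Each genotype had 2 untreated arrays, 3 arrays after 1 week and 3 arrays after 3 weeks. The labels give no age, vehicle or time of sampling for the untreated animals, so age and treatment cannot be separated in the comparisons with controls. By the schedule the 3-week animals were older than the 1-week animals and had received higher doses. Time, age and dose therefore cannot be separated in the comparisons of 3 weeks with 1 week.

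Array brightness differed between samples. The percentage of the 45598 probes well above background ran from 32.7 in wild-type control replicate 1 to 60.4 in wild-type 3-week replicate 3. It was 36.2 in wild-type control replicate 2 and 33.0 in wild-type 1-week replicate 3. The 75th percentile of the processed signal ran from 20.1 to 78.5, and no spot was saturated. Arrays of the same group correlated across genes at Pearson r 0.964 to 0.981, except that wild-type 1-week replicate 3 correlated at 0.905 and 0.908 with the other arrays of its group. The number of arrays, 2 or 3 per group, limits the precision. The labels do not state that the arrays of a group came from separate rats, so the p-values measure only the spread between these samples.

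**Figure D1:**
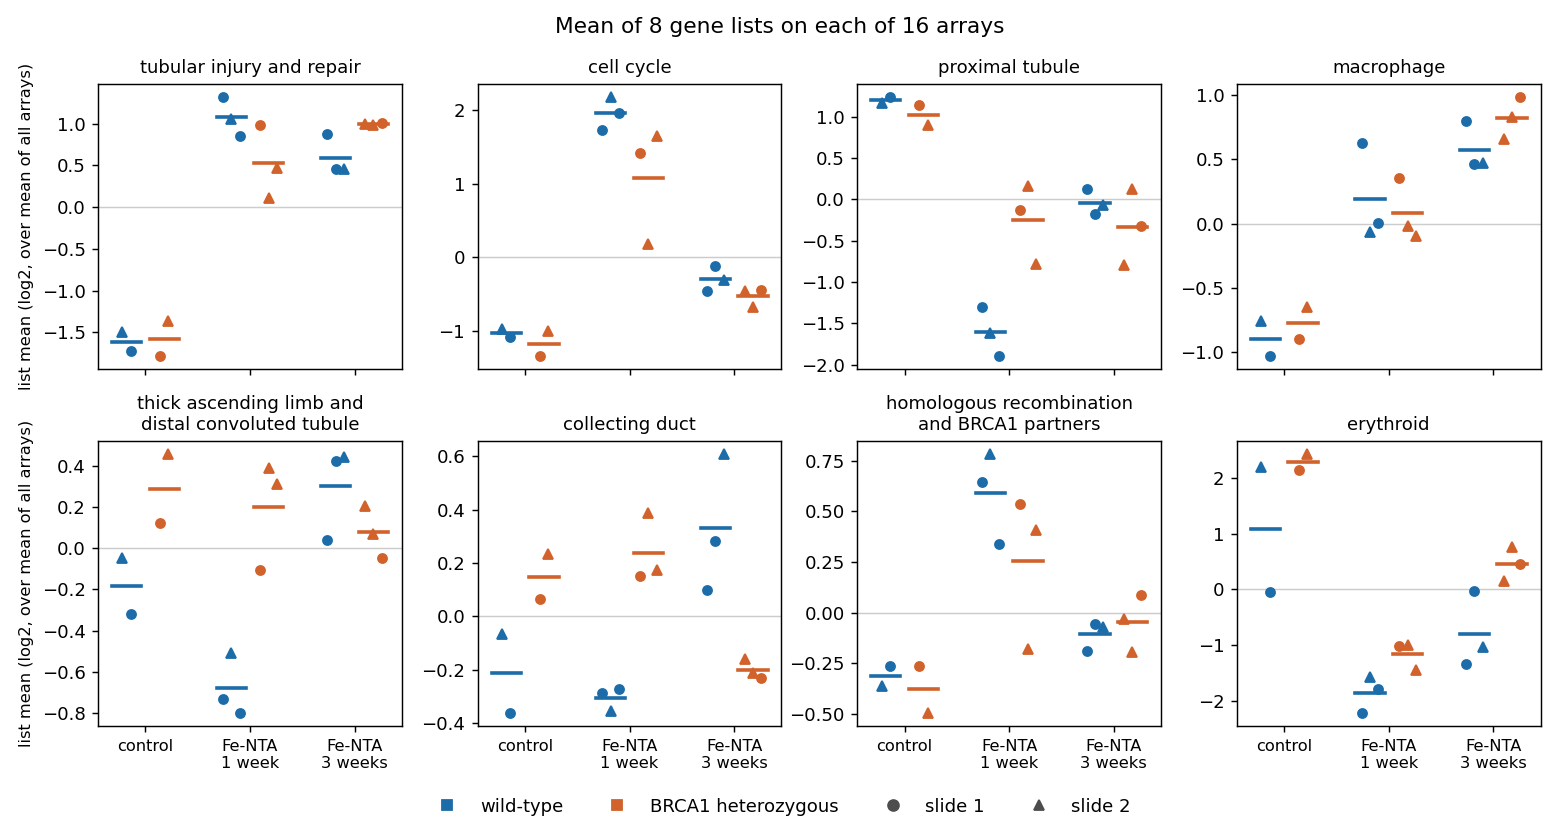
Mean scaled log2 signal of 8 gene lists on each of the 16 arrays, by genotype and time (points, arrays; bars, group means). The injury list lies higher and the proximal tubule list lower on the arrays of all treated groups than on those of the controls.

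Brca1 itself was read by 2 probes, of which 1 rose above background on any array. Its scaled log2 signal was -3.31 and -2.70 in the wild-type controls, both under the level called well above background. It was 0.26, 0.72 and -0.64 in wild-type cortex after 1 week and -1.35, -0.83 and -1.87 after 3 weeks. In heterozygous cortex it was -0.04 and -3.44 in the controls, the second under background, then -0.04, -1.61 and -0.28 after 1 week and -0.65, -1.19 and -0.81 after 3 weeks. Brca1 rose in wild-type cortex after 1 week, by at least 2.24-fold (adjusted p = 0.0059), a call that was lost without wild-type control replicate 1 (0.058), with normexp background correction (log2 0.56) and with dim values at the detection limit (log2 1.16). No other comparison called Brca1: adjusted p was 0.15 in wild-type cortex after 3 weeks, 0.41 and 0.42 in heterozygous cortex after 1 and 3 weeks, and 0.86 for the average difference between genotypes. Without heterozygous control replicate 1 it was called in heterozygous cortex after 1 and 3 weeks (adjusted p = 0.031 and 0.029), where the control left is under background, and without replicate 2 the log2 changes were -0.60 and -0.84. The position of the probe relative to the mutation is not given in the sources used here, so the signal tests nothing about the genotype labels.

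The first week of Fe-NTA in wild-type cortex (3 arrays against 2) raised markers of tubular injury and lowered transporters and enzymes of the proximal tubule. Spp1 rose by 7.28 ± 0.43 (log2 fold change ± SE, adjusted p = 1.4e-07) and the histone gene H1f5 by 5.93 ± 0.40 (6.6e-07). Havcr1, the gene of kidney injury molecule 1, was at background in both controls and at least 63.1-fold higher after treatment (adjusted p = 9.1e-08), and Lcn2 at least 50.9-fold higher (3.8e-06). Abcb1b, Fst, Il24 and Adra1d were at least 25.2-, 21.5-, 16.3- and 15.7-fold higher, with unequal values from the 2 probes of Abcb1b and of Fst. The largest falls included Hbb-bs by -5.98 ± 0.85, Cyp4a2 by -5.91 ± 0.75, Gba3 by -6.24 ± 0.56 and Tlr12 by -7.12 ± 1.06 (adjusted p from 5.1e-06 to 2.1e-04), with the probes of Gba3 between -6.44 and -1.72 and those of Tlr12 between -7.12 and -1.08. Of 16008 genes tested, 4341 changed in wild-type cortex after 1 week, 2054 up and 2287 down. The count was 1699 with normexp, 1754 with only the groups compared and 3650 (1475 up, 2175 down) with dim values at the detection limit. It was 4213 with the slide as a block, 1084 and 214 within slides 1 and 2, 2718 without control replicate 1 and 2347 without control replicate 2.

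Gene lists fixed in advance moved with these genes in wild-type cortex after 1 week. Of the 35 cell cycle genes tested 33 rose and 0 fell, also when adjusted over the list alone, with a mean log2 change of 2.99, or 1.98 with dim values set to the detection limit. Mcm5 rose by 4.15 ± 0.38 (adjusted p = 6.4e-06) and Cdk1 was at least 9.31-fold higher. Of 44 proximal tubule genes 37 fell (37 adjusted over the list alone), mean -2.81, among them Slc22a6 by -4.99 ± 0.53 (1.7e-05), and Upb1 was at least 8.27-fold lower. Of 32 injury genes 23 rose and 1 fell (25 and 2 adjusted over the list alone), mean 2.69, or 2.02 at the detection limit. Fatty acid oxidation genes fell in 18 of 26 (19 adjusted over the list alone), mean -1.57, with Ppara at -4.61 ± 0.51, and oxidative phosphorylation genes in 15 of 27 (21), mean -0.92, with Atp5po at -1.75 ± 0.26 and Sdhd at -1.53 ± 0.27. The preset correlation of camera called 12 of 25 lists, 8 up and 4 down. With an estimated correlation none held, and adjusted p of these 12 ran from 0.0934 to 0.272.

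Camera also called lists of matrix, immune, repair and red cell genes in wild-type cortex after 1 week, none of which held with an estimated correlation. Fibroblast and matrix genes rose in 17 of 26 (20 adjusted over the list alone), mean 1.60, with Pdgfrb up by 2.60 ± 0.29 (adjusted p = 2.6e-05) and Loxl2 at least 2.14-fold higher. Macrophage genes rose in 10 of 20 (13 adjusted over the list alone), mean 1.09, where Trem2 was at least 5.90-fold and Msr1 at least 1.38-fold higher. Interferon response genes rose in 6 of 16 (7), mean 1.27, with Psmb8 up by 2.99 ± 0.32 and Psmb9 by 2.60 ± 0.25. Chemokine and cytokine genes rose in 7 of 19 (7), mean 1.24, where Ccl2 was at least 4.77-fold and Icam1 at least 3.72-fold higher. Of 24 p53 targets 8 rose and 2 fell (9 and 3), mean 0.81, with Plk2 at least 8.81-fold and Cdkn1a at least 7.17-fold higher, although the 2 probes of Cdkn1a gave unequal values. Of 24 homologous recombination genes 7 rose and 2 fell (7 and 3), mean 0.90, with H2ax at least 3.06-fold higher. Erythroid genes fell in 5 of 8 (6), mean -2.94, including Hbb-b1 at -5.65 ± 0.72. With dim values at the detection limit the chemokine, p53 and homologous recombination means were 0.63, 0.45 and 0.43, and the p53 call was lost (adjusted p = 0.079). It was lost without 1-week replicate 3 too (0.057), where the mean was 0.84. Without control replicate 1 the erythroid mean was -1.81.

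The other 13 lists were not called in wild-type cortex after 1 week, at adjusted p from 0.123 to 0.955. These were iron handling, NRF2 targets and glutathione enzymes, ferroptosis regulators, thick ascending limb and distal convoluted tubule, collecting duct, podocyte, endothelium, lymphocyte, neutrophil and mast cell, adrenal and adipose, integrated stress and unfolded protein response, heat shock and metallothionein, and lysosome and autophagy. Members of several changed in both directions. Among iron handling genes Cybrd1 was at least 3.98-fold higher, among glutathione enzymes Gsta2 fell by 4.50 ± 0.48 and Gsta5 by 4.11 ± 0.46, and among ferroptosis regulators Nox4 fell by 5.61 ± 0.76 and Cbs by 2.87 ± 0.42 (adjusted p from 1.9e-05 to 1.7e-04). Atf3 was at least 4.05-fold, Gpnmb at least 3.30-fold and Asns at least 2.30-fold higher, and Fxyd2 fell by 1.85 ± 0.26. The iron handling list had a median of -0.49 and a mean of 0.05, and the podocyte list a median of -0.11 and a mean of 0.01, so median and mean differed in sign.

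After 3 weeks of Fe-NTA wild-type cortex (3 arrays against 2) still carried raised injury markers and lowered proximal tubule genes. Spp1 rose by 7.42 ± 0.43 (adjusted p = 1.4e-07), Lcn2 was at least 28.8-fold, Abcb1b at least 20.6-fold, Havcr1 at least 10.1-fold and Ces1a at least 8.73-fold higher than in controls. Cyp4a2 fell by 6.28 ± 0.75 (1.6e-04), Gsta1 changed by -4.47 ± 0.62 and Miox by -4.14 ± 0.65, and Slco1a1 and Acot5 were at least 4.08- and 3.76-fold lower. Aqp2 of the collecting duct rose by 1.82 ± 0.25 (3.7e-04) while Slc26a4 fell by 1.77 ± 0.39 (0.0081), and the distal gene Slc12a3 rose by 1.01 ± 0.27 (0.023). Tfrc fell by 2.25 ± 0.46, Mt1 by 2.13 ± 0.40 and Me1 by 1.73 ± 0.26, and Ctsd rose by 2.25 ± 0.37. Of 16008 genes 2280 changed, 1396 up and 884 down. With dim values at the detection limit 881 rose and 1047 fell, and with normexp background correction 617 and 219. The count was 2148 with the slide as a block, 304 and 3 within slides 1 and 2, 1113 and 775 without control replicates 1 and 2, and 1349 and 1506 without 3-week replicates 2 and 3. Slc12a3 lost its call without control replicate 1 or 2 and without 3-week replicate 2 or 3, and Slc26a4 without either control.

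Camera called 14 of 25 lists in wild-type cortex after 3 weeks, 9 up and 5 down, and none with an estimated correlation (adjusted p 0.108 to 0.541). Injury genes rose in 22 of 32 and fell in 1 (23 and 1 adjusted over the list alone), mean 2.21, or 1.61 at the detection limit. Fibroblast and matrix genes rose in 17 of 26 (21), mean 1.58, with Pdgfrb at 2.27 ± 0.29 and Loxl2 at least 1.44-fold higher. Macrophage genes rose in 15 of 20 (18), mean 1.48, with C1qb at 2.37 ± 0.44 and Trem2 at least 13.2-fold higher. Proximal tubule genes fell in 15 of 44 and rose in 1 (21 and 2), mean -1.24, and fatty acid oxidation genes fell in 7 of 26 (12), mean -0.77, with Etfa at -1.34 ± 0.25 and Ehhadh at -2.42 ± 0.57. Interferon genes rose in 6 of 16 (9), mean 1.21, with Psmb8 at 2.86 ± 0.32, and chemokine genes in 4 of 19 (9), mean 1.19, with Icam1 at least 3.82-fold higher. Of 24 p53 targets 8 rose (8), mean 0.87, with Cdkn1a at least 11-fold and Pmaip1 at least 1.42-fold higher. At the detection limit the chemokine and p53 means were 0.55 and 0.57. Ehhadh lost its call without control replicate 2.

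Several further list calls in wild-type cortex after 3 weeks, none held with an estimated correlation, depended on single arrays or on the treatment of dim probes. Cell cycle genes rose in 6 of 35 (8 adjusted over the list alone), mean 0.73, with Mcm5 at 1.78 ± 0.38 (adjusted p = 0.0070), a call lost without control replicate 1. The list mean was 0.25 at the detection limit, where the call was lost (0.16), and 0.0047 with normexp background correction, where camera put the list in the other direction. Oxidative phosphorylation genes fell in 5 of 27 (6), mean -0.43, but had a mean of 0.15 with normexp. Erythroid genes fell in 4 of 8 (6), mean -1.88, with Hbb-b1 at -3.12 ± 0.72 (0.010). The list and Hbb-b1 lost their calls without control replicate 1 (list mean -0.75, adjusted p = 0.168), and without control replicate 2 the list mean was -3.004. Within slides 1 and 2 it was -0.64 and -3.23. Collecting duct genes rose in 5 of 17 and fell in 2 (7 and 2), mean 0.54, a call lost without control replicate 2 (0.138) and without 3-week replicate 3 (0.112). Thick ascending limb and distal convoluted tubule genes rose in 4 of 16 (5), mean 0.49, a call lost without control replicate 2 (0.169), 3-week replicate 2 (0.077) and 3-week replicate 3 (0.127). NRF2 targets and glutathione enzymes fell in 12 of 34 and rose in 4 (12 and 4), mean -0.38, a call kept without each array in turn and at the detection limit but lost without the filter on dim probes.

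In heterozygous cortex 1 week of Fe-NTA (3 arrays against 2) raised injury genes and lowered globin genes. Spp1 rose by 6.39 ± 0.43 (adjusted p = 8.7e-07), Lcn2 by 5.73 ± 0.57 (7.2e-05) and Fst by 5.65 ± 0.33 (1.8e-07), the latter with probes at 3.13 and 5.65. Havcr1 was at least 30-fold and Abcb1b at least 27.3-fold higher, the latter with unequal values from its 2 probes. Serpina3n rose by 5.54 ± 1.36 (0.023) on 1 probe, while its other probe gave 0.08. Hbb-bs fell by 6.14 ± 0.85 (6.7e-04) and Hbb-b1 fell by 5.11 ± 0.72, and Hba-a3 was at least 6.25-fold lower. Slco1a1 was at least 8.43-fold lower. Of 16008 genes 1196 changed, 684 up and 512 down, or 479 and 637 with dim values at the detection limit and 176 and 261 with normexp. The count was 1209 with the slide as a block and 126 and 28 within slides 1 and 2. It was 367 and 453 without control replicates 1 and 2, and 788 and 540 without 1-week replicates 1 and 3. Serpina3n lost its call without control replicate 1 or 2 and without 1-week replicate 3.

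Camera called 13 of 25 lists in heterozygous cortex after 1 week, 9 up and 4 down, and none with an estimated correlation (adjusted p 0.0510 to 0.408). Cell cycle genes rose in 26 of 35 (32 adjusted over the list alone), mean 2.26, or 1.23 at the detection limit, with Cdk1 at 3.36 ± 0.38 (1.7e-04) and Prc1 at least 2.12-fold higher. Injury genes rose in 18 of 32 and fell in 1 (23 and 1), mean 2.10, and fibroblast and matrix genes rose in 15 of 26 (21), mean 1.26, with Fn1 at 3.12 ± 0.47 and Timp1 at 2.51 ± 0.40. Proximal tubule genes fell in 11 of 44 (22), mean -1.27, with Cyp4a2 at -3.92 ± 0.75 (0.0061) and Slc22a6 at -2.59 ± 0.53 (0.0085). Erythroid genes fell in 6 of 8 (7), mean -3.44, or -2.88 at the detection limit. Macrophage genes rose in 8 of 20 and fell in 1 (12 and 2), mean 0.85, or 0.57 at the detection limit, with Trem2 at 3.16 ± 0.55. Fatty acid oxidation genes fell in 3 of 26 (8), mean -0.61, with Echs1 at -1.07 ± 0.26 (0.021). Without control replicate 1 the calls of Slc22a6, Trem2 and Echs1 were lost, without control replicate 2 those of Cyp4a2 and Echs1, and without 1-week replicate 1 or 3 that of Echs1.

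Camera also called 6 lists of stress, repair, immune and respiration genes in heterozygous cortex after 1 week, none of them with an estimated correlation. Of 24 p53 targets 7 rose and 1 fell (10 and 4 adjusted over the list alone), mean 0.88, with Cdkn1a at 3.77 ± 0.37 (adjusted p = 7.2e-05) and Pmaip1 at least 1.32-fold higher. Homologous recombination genes rose in 5 of 24 (6), mean 0.63, with Bard1 at 2.13 ± 0.44 (0.0090). Integrated stress genes rose in 4 of 21 and fell in 2 (6 and 2), mean 0.39, with Asns at 1.42 ± 0.32 (0.016) and Atf3 at least 2.16-fold higher. Interferon genes rose in 4 of 16 (4), mean 0.75, with Psmb8 at 1.74 ± 0.32 (0.0049), and chemokine genes in 4 of 19 (5), mean 0.79, with Ccl2 at least 1.93-fold higher. Oxidative phosphorylation genes had a mean of -0.39 with 0 of 27 changed singly (0). Among genes of other lists Srxn1 rose by 1.95 ± 0.28, Akr7a3 fell by 2.37 ± 0.42, Cbs fell by 1.99 ± 0.42 and Gpnmb was at least 2.31-fold higher. At the detection limit the means were 0.46 for p53, 0.41 for chemokine, 0.20 for homologous recombination and 0.16 for integrated stress genes, the last 2 not called (0.092 and 0.078). Without 1-week replicate 1 the chemokine mean was 0.48. The homologous recombination call was lost without control replicate 2 (0.057) and 1-week replicate 1 (0.069), and the integrated stress call without control replicate 2 (0.060) and 1-week replicate 3 (0.085). Single-gene calls were lost for Bard1, Psmb8, Cbs, Ccl2 and Asns without control replicate 1, for Akr7a3, Ccl2 and Asns without control replicate 2, and for Asns without 1-week replicate 1.

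After 3 weeks heterozygous cortex (3 arrays against 2) carried raised injury genes. Spp1 rose by 7.72 ± 0.43 (adjusted p = 8.0e-08), Car3 by 6.79 ± 0.55 (3.5e-06, probes at 3.67 and 6.79) and Lcn2 by 6.36 ± 0.57 (8.8e-06). Ces1a and Serpina10 were each at least 19.6-fold and Havcr1 at least 16.2-fold higher. Slco1a1 and Acot5 were at least 8.43- and 2.44-fold lower, Cyp4a2 fell by 4.79 ± 0.75 (8.8e-04) and Miox by 3.85 ± 0.65 (0.0014). Of distal and collecting duct genes Atp6v1g3 fell by 1.48 ± 0.25, Fxyd2 by 1.39 ± 0.26, Slc26a4 by 1.86 ± 0.39 and Klk1 by 2.12 ± 0.45 (adjusted p 0.0017 to 0.0063). Gpx2 rose by 3.37 ± 0.56, Srxn1 rose by 1.71 ± 0.28, Ptgs2 fell by 2.19 ± 0.40 and Cbs fell by 2.27 ± 0.42, and Gpnmb was at least 4.00-fold higher. Of 16008 genes 2539 changed, 1496 up and 1043 down. The count was 1561 with normexp, 3882 with only the groups compared, 2640 with the slide as a block, 251 and 277 within slides 1 and 2, 813 and 964 without control replicates 1 and 2, and 1284 without 3-week replicate 3. Klk1 lost its call without control replicate 1 and Slc26a4 without control replicate 2.

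Camera called 11 of 25 lists in heterozygous cortex after 3 weeks, 7 up and 4 down, and none with an estimated correlation (adjusted p 0.108 to 0.639). Injury genes rose in 25 of 32 and fell in 1 (25 and 2 adjusted over the list alone), mean 2.57, or 1.90 at the detection limit. Fibroblast and matrix genes rose in 19 of 26 (20), mean 1.71, with Fn1 at 4.30 ± 0.47 and Timp1 at 3.08 ± 0.40, and macrophage genes in 15 of 20 with 2 falling (17 and 2), mean 1.60, with Trem2 at 4.31 ± 0.55. Proximal tubule genes fell in 13 of 44 (25), mean -1.35, and fatty acid oxidation genes in 10 of 26 (10), mean -0.88, with Acaa2 at -1.80 ± 0.34 and Ehhadh at -2.69 ± 0.57. Interferon genes rose in 11 of 16 (13), mean 1.52, with Psmb8 at 2.79 ± 0.32, and chemokine genes in 10 of 19 (13), mean 1.42, with Icam1 at 2.40 ± 0.35. Of 24 p53 targets 11 rose and 1 fell (12 and 3), mean 0.96, with Cdkn1a at 3.39 ± 0.37 and Pmaip1 at least 2.42-fold higher. Erythroid genes fell in 5 of 8 (6), mean -1.83, with Hbb at -2.66 ± 0.73 (0.025). Cell cycle genes rose in 5 of 35 (5), mean 0.65, or 0.27 and not called at the detection limit (0.32), and oxidative phosphorylation genes had a mean of -0.38 with 0 changed singly (0). The chemokine and p53 means were 0.79 and 0.60 at the detection limit. The homologous recombination list was not called. Without control replicate 1 the calls of Ehhadh, Hbb and the cell cycle list (0.063) were lost, without control replicate 2 that of Hbb, without 3-week replicate 1 those of Hbb and oxidative phosphorylation (0.074), and without 3-week replicate 3 that of Hbb.

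The change from 1 to 3 weeks within wild-type cortex (3 arrays against 3) was a fall of proliferation genes and a rise of tubule genes. Age and dose differed between these groups too. Camera called 8 of 25 lists, none with an estimated correlation (adjusted p 0.0968 to 0.477). Ccna2 fell by 3.54 ± 0.43 (adjusted p = 9.7e-04), Mcm6 by 3.72 ± 0.52 (0.0020), Fosl1 by 3.67 ± 0.44 (9.7e-04), Prc1 by 3.35 ± 0.44 and Cdk1 by 2.75 ± 0.34, and Dhrs9 was at least 1.85-fold lower. Pck1 rose by 3.91 ± 0.58 (0.0020), Slc34a3 by 3.66 ± 0.66, Slc34a1 by 3.46 ± 0.50, Fn3k by 3.34 ± 0.35 and Ppara by 2.95 ± 0.45, and Upb1 was at least 4.29-fold higher. Cell cycle genes fell in 32 of 35 (34 adjusted over the list alone), mean -2.26. Proximal tubule genes rose in 23 of 44 (36), mean 1.56, thick ascending limb and distal genes in 7 of 16 (7), mean 0.98, with Wnk1 at 1.64 ± 0.25, and collecting duct genes in 6 of 17 with 1 falling (10 and 1), mean 0.63, with Hsd11b2 at 1.82 ± 0.33 and Aqp2 at 1.06 ± 0.22. Fatty acid oxidation genes rose in 7 of 26 (13), mean 0.79, with Echs1 at 1.21 ± 0.23, and oxidative phosphorylation genes in 5 of 27 (7), mean 0.49, with Sdhb at 1.13 ± 0.28 and Cox5b at 0.89 ± 0.23, a list mean of 0.32 without 1-week replicate 3. Homologous recombination genes fell in 4 of 24 (7), mean -0.70, with H2ax at -1.62 ± 0.31. Injury genes fell in 4 of 32 and rose in 1 (5 and 1), mean -0.48, with Havcr1 at -2.65 ± 0.41 and Vim at -2.36 ± 0.35. Hmox1 fell by 1.85 ± 0.45 (0.019).

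In total 1331 genes changed between 1 and 3 weeks in wild-type cortex, 886 up and 445 down. The count was 669 with normexp, 457 with only the groups compared, 1222 with the slide as a block, 135 and 0 within slides 1 and 2, and 795, 597 and 648 without 3-week replicates 1, 2 and 3. Sdhb and Hmox1 lost their calls without 1-week replicate 3, Sdhb, Cox5b and Hmox1 without 3-week replicate 1 or 2, and 2 of these 3 genes without 3-week replicate 3.

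In heterozygous cortex the change from 1 to 3 weeks (3 arrays against 3) reached 49 genes, 30 up and 19 down. Sctr and Slc13a5 were at least 1.15- and 1.48-fold higher (adjusted p = 0.0011 and 0.0054), and Cdk1 fell by 2.49 ± 0.34 (0.0070). These 3 kept their calls whichever array was left out. Mmp7 rose by 4.97 ± 0.73 (0.011), Hbb-bs by 4.00 ± 0.76, A2m by 3.46 ± 0.59, Tf by 2.83 ± 0.51 and Cxcl13 by 2.05 ± 0.40, and Prc1, Ccna2, Rrm2 and Kif20a fell by 2.43 ± 0.44, 2.42 ± 0.43, 2.42 ± 0.46 and 2.19 ± 0.35. Il31ra and Cdkn3 were at least 1.08- and 1.26-fold lower. The 11 others all lost their calls without 1-week replicate 3, and 2 to 9 of them without each other array. The count was 84, 83 and 15 without 1-week replicates 1, 2 and 3, and 22, 16 and 15 without 3-week replicates 1, 2 and 3. It was 40 with the slide as a block and 2 and 0 within slides 1 and 2. Of the 49, 61.2% rose, against 82.8% of 29 with normexp, 81.4% of 43 with dim values at the detection limit, 92.0% of 25 with only the groups compared and 22.9% of 83 without 1-week replicate 2, where most fell.

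Camera called 11 of 25 lists between 1 and 3 weeks in heterozygous cortex, 6 up and 5 down, none with an estimated correlation (adjusted p 0.161 to 0.527). Cell cycle genes fell in 8 of 35 (29 adjusted over the list alone), mean -1.61, or -0.96 at the detection limit. The rises were erythroid (mean 1.61, 0 of 8 singly, 6 over the list alone), interferon (0.78, 0 of 16, 6), macrophage (0.75, 0 of 20, 3), chemokine (0.63, 1 of 19, 1), injury (0.47, 0 of 32, 7) and fibroblast and matrix genes (0.45, 0 of 26, 0). The falls besides cell cycle were collecting duct (-0.44, 0 of 17, 5), endothelium (-0.31, 0 of 15, 1), homologous recombination (-0.30, 0 of 24, 2) and fatty acid oxidation genes (-0.26, 0 of 26, 0). Within slides 1 and 2 the injury mean was 0.02 and 0.70. At the detection limit the chemokine mean was 0.38 and the homologous recombination list, at -0.13, was not called (0.060). The chemokine mean was 0.38 without 1-week replicate 2, the homologous recombination mean -0.52 without 1-week replicate 2, and the endothelium and fatty acid oxidation means -0.48 and -0.40 without 1-week replicate 3. The injury call was lost without 1-week replicate 2 (mean 0.27, adjusted p = 0.084), the matrix call without 1-week replicate 3 (mean 0.30) and 3-week replicates 1 and 3, the endothelium and fatty acid oxidation calls without 1-week replicates 1 and 2 (endothelium mean -0.19 without the latter) and 3-week replicate 1 (fatty acid oxidation mean -0.15), and the homologous recombination call without 1-week replicates 1 (mean -0.16) and 3 and 3-week replicate 2.

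The Fe-NTA responses of the genotypes, which share no array, were similar across genes. Across the 16008 genes the log2 fold changes of wild-type and heterozygous cortex correlated at Pearson r 0.811 after 1 week (0.721 and 0.651 within slides 1 and 2) and 0.797 after 3 weeks (0.759 and 0.676), where genes are not independent replicates. After 1 week 617 genes rose in both genotypes against 87.8 expected if the calls were independent, and 458 fell in both against 73.2. After 3 weeks 887 rose in both against 130.5, and 480 fell in both against 57.6. Of the genes called in wild-type cortex, 96.5% to 98.4% had the same sign in heterozygous cortex.

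**Figure D2:**
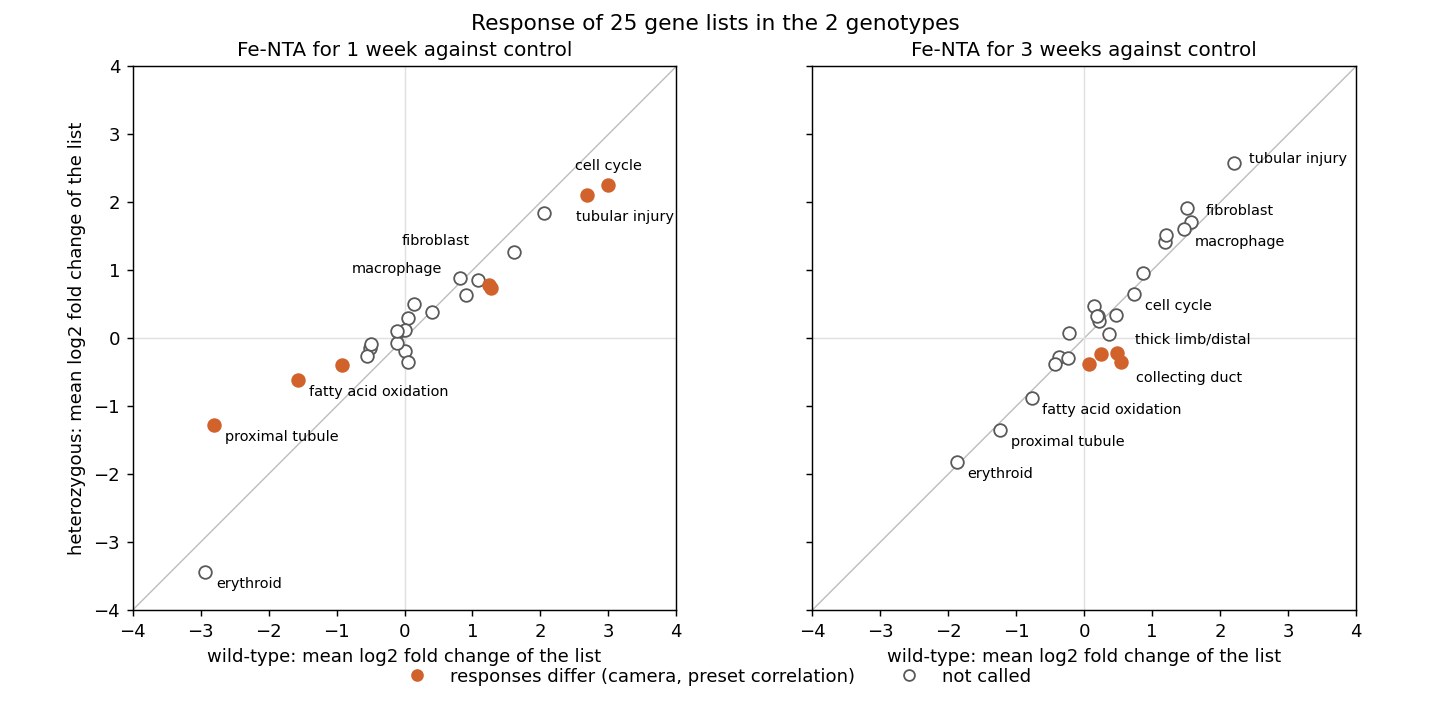
Mean log2 fold change of each of the 25 lists in wild-type (x axis) and heterozygous cortex (y axis) after 1 and 3 weeks of Fe-NTA, each point a list, filled where camera with the preset correlation called the difference between genotypes. The proximal tubule list lies at -2.81 and -1.27 after 1 week and at -1.24 and -1.35 after 3 weeks.

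Between the genotypes, proximal tubule genes were higher in heterozygous than in wild-type cortex after 1 week (3 arrays against 3). Pck1 was higher by 3.71 ± 0.58 (log2, SE, adjusted p = 0.023), Ppara by 3.10 ± 0.45 (0.017), G6pc1 by 3.01 ± 0.48, Miox by 2.78 ± 0.58, Dio1 by 2.72 ± 0.46 and Ehhadh by 2.56 ± 0.51, and Upb1 and Ces1e were at least 4.07- and 1.54-fold higher. H1f5 was lower, at -2.10 ± 0.36 (0.028), as were Cxcl3 at -2.06 ± 0.36, Tubb6 at -1.84 ± 0.34, Vim at -1.72 ± 0.35 and Itga3 at -1.23 ± 0.24. Wnk1 and Atp6v0d2 were higher by 1.23 ± 0.25 and 1.09 ± 0.21. In total 90 genes differed, 79 higher and 11 lower in heterozygous cortex, or 24 and 22 with dim values at the detection limit and 0 and 2 with normexp. The count was 34 with the slide as a block and 0 within either slide, and across all genes the differences within the 2 slides correlated at Pearson r 0.026. It was 138, 21 and 4 without wild-type replicates 1, 2 and 3, and 11, 1 and 140 without heterozygous replicates 1, 2 and 3. Of the 15 genes named here 3, 12 and 13 lost their calls without wild-type replicates 1, 2 and 3, and 12, 15 and 2 without heterozygous replicates 1, 2 and 3.

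Camera called 10 of 25 lists between genotypes after 1 week, 5 up and 5 down, none with an estimated correlation (adjusted p 0.0629 to 0.509). The proximal tubule list had a mean difference of 1.35 (1.47 and 1.31 within slides 1 and 2) with 6 of 44 genes higher (30 adjusted over the list alone). Fatty acid oxidation (mean 0.83, 2 of 26, 13 over the list alone), thick ascending limb and distal (0.88, 1 of 16, 9), collecting duct (0.54, 1 of 17, 3) and oxidative phosphorylation genes (0.36, 0 of 27, 0) were also higher in heterozygous cortex. Cell cycle (-0.88, 0 of 35, 0), injury (-0.55, 2 of 32, 5), interferon (-0.42, 0 of 16, 2), chemokine (-0.36, 0 of 19, 1) and homologous recombination genes (-0.33, 0 of 24, 0) were lower. Without heterozygous replicate 2 the cell cycle and injury means were -0.42 and -0.35, and within slides 1 and 2 they were -0.43 and -1.27, and -0.10 and -0.76. Without wild-type replicate 3 the means were 0.19 for oxidative phosphorylation, -0.69 for interferon and -0.58 for chemokine genes, and the last was -0.66 without heterozygous replicate 1. Within slide 1 the chemokine mean was 0.29 and the homologous recombination mean 0.04, the opposite sign. The chemokine call was lost without wild-type replicates 1 (mean -0.17) and 2 and heterozygous replicates 2 (mean -0.11) and 3, the homologous recombination call without wild-type replicate 2 and heterozygous replicate 2 (mean -0.12), and the interferon call without wild-type replicate 1 (mean -0.19).

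Between untreated genotypes (2 arrays against 2) limma called 0 genes, with 738 at an unadjusted p under 0.05, 40 with dim values at the detection limit and 2 without wild-type control replicate 2. Camera called 3 lists higher in heterozygous cortex, none with an estimated correlation (adjusted p 0.528). These were erythroid (mean 1.21), thick ascending limb and distal (0.47, with Kcnj1 at 0.79 ± 0.27 and Slc12a3 at 0.84 ± 0.30, neither called) and collecting duct genes (0.36, with Foxi1 at 0.82 ± 0.39 and Aqp2 at 0.53 ± 0.27, neither called), with 0 genes called in each, also over the list alone. Without wild-type control replicate 2 no list of the 3 was called (erythroid mean 0.08, collecting duct mean 0.22), without replicate 1 the erythroid mean was 2.34, and without heterozygous control replicate 2 the distal (mean 0.31) and collecting duct calls were lost.

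After 3 weeks (3 arrays against 3) limma called 0 genes between genotypes, with 931 at an unadjusted p under 0.05, 3 with dim values at the detection limit, 1 with normexp and 1 without wild-type replicate 3. Camera called 10 lists, none with an estimated correlation (adjusted p 0.115 to 0.665). Collecting duct genes were lower in heterozygous cortex (mean -0.53, 0 of 17 singly, 4 over the list alone, with Scnn1a at -1.02 ± 0.27 and Scnn1g at -0.92 ± 0.24, neither called). Proximal tubule (-0.29), fatty acid oxidation (-0.23), thick ascending limb and distal (-0.23) and cell cycle genes (-0.23) were lower, the last at 0.08 among probes above background on all arrays. Erythroid (1.26, 5 up and 1 down over the list alone), fibroblast and matrix (0.42, with Fn1 at 1.62 ± 0.42, not called), interferon (0.41), injury (0.40) and iron handling genes (0.28, with Tf at 2.07 ± 0.51, not called) were higher. Only the collecting duct, erythroid, injury and interferon calls stayed under adjusted p 0.05 whichever of the 6 arrays was left out. The cell cycle list had a mean of -0.01 at the detection limit and was not called (0.55). The proximal tubule mean was -0.52 without heterozygous replicate 2, the interferon mean 0.63 without heterozygous replicate 1 and the distal mean -0.36 without wild-type replicate 1. The proximal tubule and fatty acid oxidation calls were lost without heterozygous replicate 1 (means -0.06 and -0.12), the matrix call without heterozygous replicate 3 (mean 0.28), the cell cycle call without wild-type replicate 2 (mean -0.14) or heterozygous replicate 2, the iron handling call without wild-type replicate 2 and heterozygous replicates 2 and 3, and the distal call without wild-type or heterozygous replicates 2 and 3.

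Averaged over the 3 conditions, limma called 0 genes between genotypes, with 1210 at an unadjusted p under 0.05 and 23 with dim values at the detection limit. Camera called 5 lists, none with an estimated correlation (adjusted p 0.231 to 0.843). Erythroid genes were higher in heterozygous cortex (mean 1.06, 6 of 8 over the list alone), as were thick ascending limb and distal (0.38, 2 of 16, with Kcnj1 at 0.52 ± 0.14, not called over all genes), proximal tubule (0.29, 0 of 44) and fibroblast and matrix genes (0.22, 0 of 26), and cell cycle genes were lower (-0.42, 0 of 35, or -0.27 at the detection limit and also without heterozygous 1-week replicate 2). Without wild-type control replicate 2 the erythroid mean was 0.68. The proximal tubule call was lost without heterozygous 1-week replicate 2 or 3-week replicate 2. The matrix call was lost without any 1 of 8 arrays: control replicate 2, 1-week replicate 2 and 3-week replicates 2 and 3 of the wild type, and control replicate 1, 1-week replicate 1 and 3-week replicates 1 and 3 of the heterozygotes.

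Whether the response to Fe-NTA differed between genotypes was tested with interaction terms over 10 arrays at each time. Limma called 0 genes after 1 week and 0 after 3 weeks, with 1218 and 759 at an unadjusted p under 0.05, 16 and 18 with dim values at the detection limit, 1 at 3 weeks with normexp, and 6 after 1 week without heterozygous replicate 3. None of Tfrc, Hmox1, Gpx4, Cdkn1a and Havcr1 was called at either time (lowest adjusted p 0.905 and 0.977), and Slc7a11 was too dim to test. After 1 week camera called 7 lists, none with an estimated correlation (adjusted p 0.147 to 0.557). The interaction mean was 1.53 for proximal tubule genes (1.57 within each slide, 12 of 44 over the list alone), 0.95 for fatty acid oxidation (6 of 26) and 0.53 for oxidative phosphorylation (0 of 27), which fell more in wild-type cortex. It was -0.73 for cell cycle (0 of 35), -0.59 for injury (1 of 32), -0.52 for interferon (1 of 16) and -0.45 for chemokine genes (0 of 19), which rose more in wild-type cortex. Within slides 1 and 2 it was -0.17 and -1.24 for cell cycle, -0.04 and -0.89 for injury, -0.69 and -0.46 for interferon, and 0.20, the opposite sign, and -0.83 for chemokine genes. It was 1.08 and 0.89 for fatty acid oxidation and 0.69 and 0.30 for oxidative phosphorylation. Without heterozygous 1-week replicate 2 the interaction was -0.28 for cell cycle and -0.38 for injury genes, and it was -0.38 for injury genes without heterozygous control replicate 2. Without wild-type 1-week replicate 3 it was 0.35 for oxidative phosphorylation, -0.80 for interferon and -0.67 for chemokine genes. For chemokine genes it was -0.75 without heterozygous 1-week replicate 1, and -0.22 and not called at the detection limit. The chemokine call was lost without 6 of the 10 arrays (wild-type control replicate 2 and 1-week replicates 1 and 2, heterozygous control replicate 2 and 1-week replicates 2 and 3), with means of -0.26 without wild-type 1-week replicate 1 and -0.20 without heterozygous 1-week replicate 2. The interferon call was lost without wild-type control replicate 2 (-0.27), wild-type 1-week replicate 1 (-0.30) and heterozygous control replicate 2.

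After 3 weeks camera called the interaction for 4 lists, all negative, none with an estimated correlation (adjusted p 0.0669 to 0.755). It was -0.89 for collecting duct genes (6 of 17 over the list alone) and -0.70 for thick ascending limb and distal genes (1 of 16), whose means were 0.54 and 0.49 in wild-type and -0.35 and -0.21 in heterozygous cortex, the latter not called. It was -0.49 for podocyte and -0.45 for endothelium genes (0 of 14 and 0 of 15), the latter -0.23 and not called at the detection limit (0.10). The podocyte call was lost without wild-type control replicate 2 (-0.32), wild-type 3-week replicates 2 and 3, either heterozygous control and heterozygous 3-week replicates 1 and 2, and the endothelium call without either wild-type control, wild-type 3-week replicates 2 and 3, heterozygous control replicate 2 and heterozygous 3-week replicates 1 and 2.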

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

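The tests of a single outlying array, of the slide and of other nephron segments for the proximal tubule, and of the depth of the cortex taken for the collecting duct, were chosen after the result was seen.

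Camera called a difference between the genotypes' responses to Fe-NTA for 11 lists, which is why they are set out here. After 1 week the mean interaction (log2, heterozygous minus wild-type) was 1.53 for proximal tubule, 0.95 for fatty acid oxidation, 0.53 for oxidative phosphorylation, -0.73 for cell cycle, -0.59 for tubular injury and repair, -0.52 for interferon response, and -0.45 for chemokines and cytokines. After 3 weeks it was -0.89 for collecting duct, -0.70 for thick ascending limb and distal convoluted tubule, -0.49 for podocyte and -0.45 for endothelium. None of the 11 was called with an estimated correlation, and limma called 0 single genes in either interaction (1218 and 759 at an unadjusted p under 0.05).

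The proximal tubule list was higher in heterozygous than in wild-type cortex after 1 week by a mean of 1.35. The tables argue against an outlying array and the slide as its whole cause, and less firmly against a shift between nephron segments. Without wild-type replicate 3, the array least like the others of its group, the mean was 1.21 (camera adjusted p = 4.4e-17), and the lower of the means within the 2 slides was 1.31. Wild-type pieces holding less proximal tubule and more of the other segments would put the other nephron lists lower in heterozygous cortex, but the lower of their 2 means was 0.54. Between controls these lists were already higher in heterozygous cortex, by 0.47 (distal) and 0.36 (collecting duct). Their interactions after 1 week were 0.40 and 0.18, neither called. A lower share of all tubule segments together is not addressed by this test. A weaker response of BRCA1+/- cortex, or an effect of the selection of animals, stays open as a hypothesis, and the estimated correlation (adjusted p = 0.072) and the split of the same 6 arrays described with the other observations leave open how far it goes beyond these 6 arrays.

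The collecting duct list responded to 3 weeks of Fe-NTA with a mean of 0.54 in wild-type and -0.35 in heterozygous cortex, the latter not called. The wild-type call was itself lost without control replicate 2 or 3-week replicate 3. The interaction is the genotype difference after 3 weeks (-0.53) minus that between controls (0.36, 2 arrays against 2). For the distal list these were -0.23 and 0.47, so there the larger part came from the controls. The tables argue against the slide, since the higher of the interaction means within the 2 slides was -0.85, and against a single array, since the highest camera adjusted p with any 1 of the 10 arrays left out was 9.0e-06. A difference in the depth of the cortex taken between groups is a candidate explanation, since the thick ascending limb and distal list had an interaction of -0.70, the same sign. The podocyte and proximal tubule lists had interactions of -0.49 and -0.11, the latter not called, and whether depth would give these too was not tested. A biological difference between genotypes stays open, and was not tested apart from depth.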

How the results depend on the processing

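Chosen after the result was seen were 4 settings: testing only probes well above background on all arrays, flooring values at the detection limit, scaling on the median of probes above background, and the slide block for the lists. All other settings were fixed before the data were examined.

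Leaving out each array in turn gave 2347 to 5352 genes for wild-type cortex after 1 week, 775 to 1564 after 3 weeks, 367 to 1112 and 813 to 1979 for heterozygous cortex, 597 to 1983 for wild-type 3 weeks against 1 week and 15 to 84 for heterozygous. For the genotype it gave 0 to 2 (control), 1 to 140 (1 week), 0 to 1 (3 weeks) and 0 to 0 (average), and for the interactions 0 to 6 and 0 to 0. List calls ran from 48 to 50 (main value 50) for treatment, 16 to 23 (19) for time and 33 to 44 (39) for genotype, and the correlation of responses from 0.735 to 0.829 and 0.755 to 0.802. Of 1160 named-gene values 985 kept direction and call, 169 lost the call, 2 gained it and 4 changed sign. Here and below, the interactions enter these values only as the number called among the 5 fixed genes tested. Sign changes of those genes were not counted. With a control left out, the lone control array is assumed to vary like the other groups. The low counts after leaving out an array follow in part from fewer samples.

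Normexp lowered the counts to 1699 and 836 (wild-type, 1 and 3 weeks), 437 and 1561 (heterozygous), 669 and 29 (3 weeks against 1 week) and 2 (genotype at 1 week), and gave 1 for the genotype at 3 weeks, 1 for the interaction at 3 weeks and 0.773 for the correlation at 3 weeks. Without the filter on dim probes, which tests more genes, the counts were 2655, 970, 454, 1068, 471 and 12, then 1 for the genotype at 1 week, with 71 genotype list calls and correlations of 0.663 and 0.602. Without it the median of all genes moved to -0.34 in wild-type cortex at each time and -0.35 between control genotypes. With only the groups of the comparison the counts were 1754 and 3704 (wild-type), 3882 (heterozygous, 3 weeks), 457 and 25 (time) and 0 (genotype at 1 week). With only probes above background on all arrays, which tests fewer genes, they were 2660, 1319, 584 and 1649 for treatment and 11 for heterozygous time, with a correlation of 0.820 at 3 weeks. With the floor they were 40, 46, 3 and 23 for the genotype (control, 1 week, 3 weeks, average) and 16 and 18 for the interactions, with correlations of 0.840 and 0.828. Heterozygous 3 weeks against 1 week gave 20 genes with quantile normalization and 82 with trend and robust eBayes, which gave 166 for the genotype at 1 week. The slide block gave 34 for the latter. The estimated correlation left 0 list calls for treatment, 0 for time and 0 for genotype. Apart from the number of genes or samples, the cause was not tested.

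Brca1 changed sign with normexp in wild-type cortex at 3 weeks (-0.0395), heterozygous cortex at 3 weeks (-0.0277) and the genotype average (-0.0188), and with the floor in heterozygous cortex at 3 weeks (-0.29). It did so without heterozygous control replicate 2 at 1 week (-0.60) and 3 weeks (-0.84), and without replicate 1 between control genotypes (-0.44) and on average (-0.24), in no case called. Without replicate 1 the model gave 2.80 and 2.56 in heterozygous cortex at 1 and 3 weeks, both called, and without replicate 2 it gave 2.97 between control genotypes and 0.90 on average, neither called. These rest on substitute values of controls under background and are no measure of size. Its call in wild-type cortex at 1 week was lost with normexp (0.56) and the floor (1.16). With normexp camera gave the other direction, uncalled, for 3 lists: cell cycle (mean 0.0047) and oxidative phosphorylation (0.15) in wild-type cortex at 3 weeks, and chemokines in the interaction at 1 week (-0.0811). The means of the first and last kept their sign. With only probes above background on all arrays camera did so for the cell cycle list between genotypes at 3 weeks (0.0843). The cause was not tested.

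Of 212 named-gene values, those that kept direction and call were 149 with normexp, 202 with quantile normalization, 172 without the filter, 212 with every probe, 212 with the authors' table, 201 with the slide block, 211 with trend, 177 with only the groups compared, 170 with the floor and 210 with median scaling, and 87 of 88 with only probes above background on all arrays. A list result counted as kept where the list stayed uncalled, whatever its direction, or held its call and direction. Of 300 list results, 265, 291, 237, 299, 294, 286 and 296 were kept with normexp, quantile normalization, no filter, the authors' table, the slide block, the floor and median scaling. With the estimated correlation 192 lists stayed uncalled and the other 108 lost their call. Of these 300, 288 had a value with only probes above background on all arrays, and 249 of them were kept in the same sense.

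The replicate number as a block, a paired fit, kept 207 of 212 named-gene values and 297 of 300 list results and called 80 genes for heterozygous 3 weeks against 1 week. The numbers do not pair the arrays: residuals of arrays with the same number correlated at a mean of -0.0073 over 36 pairs, and those with different numbers at 0.0036 over 70 pairs. For arrays on the same slide the mean was 0.043 over 52 pairs, and for those on different slides -0.041 over 54 pairs.

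Signal over background limits genes near the detection limit, since only 12172 of 45598 probes were well above background on all 16 arrays, and the share on single arrays ran from 32.7 to 60.4%.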

Other observations

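The tests of blood left in the tissue and of array brightness as a covariate were chosen after the result was seen.

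Splits of the same arrays show how far the counts rest on the grouping. For 3 weeks against 1 week the 10 splits of 6 arrays are too few for a share under 0.05. The real split called 1331 genes in wild-type cortex and the highest of the others 1, and in heterozygous cortex the values were 49 and 0, so 1 split in each reached the real count. For the genotype after 1 week, also with 10 splits, too few for such a share, the real split called 90 and the highest other 1289, so 2 splits reached the real count. That split set wild-type replicates 1 and 2 with heterozygous replicate 1 against wild-type replicate 3 with heterozygous replicates 2 and 3. It does not follow the slides and, calling many more genes than the real one, points to a structure of the samples other than genotype. After 3 weeks the real split called 0 and the highest other of the 10 called 1, and for the genotype average the real count was 0 and the highest of 100 draws 7. A count of 0 is reached by every split (10 of 10 and 100 of 100), so these say nothing about chance.

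The first 2 principal components of the 16 arrays held 39.5% and 22.6% of the variance. Wild-type 1-week replicate 3 stood apart on the second, at 118.0, against 0.92 and 20.1 for the others of its group and at most 54.8 in size for any other array.

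Erythroid genes were lower on the treated arrays, by a mean of 2.94 and 1.88 in wild-type and 3.44 and 1.83 in heterozygous cortex after 1 and 3 weeks, where the wild-type values were 1.81 and 0.75 without control replicate 1. The tables argue against array brightness as the whole cause after 1 week: with the percentage of probes above background as a covariate of a linear model over the 16 arrays the falls were 2.86 and 3.44, and the highest p was 0.0073 over all arrays and with each control left out. After 3 weeks the covariate moved the falls little, to 1.68 and 1.81, but the highest p over the 16 arrays and with each control left out was 0.254, for a wild-type fall of 0.67 without control replicate 1, so brightness cannot be told apart, as also by Pearson r -0.16 between deviations from group means (permutation p = 0.642, Spearman rho -0.10, p = 0.758). Blood left in the pieces stays a candidate explanation, since the list mean ranged over 2.26 between the 2 wild-type controls, more than 1.83, the smallest fall, although the heterozygous groups ranged over only 0.30, 0.435 and 0.60. A fall of red cells or of their precursors after Fe-NTA stays open and was not tested.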
